A study of Mus musculus with 10 samples.

How the data were processed

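RNA from CD3+ T cells of mouse spleen was measured on Affymetrix arrays, in 5 wild-type and 5 KLF13 knockout samples that the labels name as separate mice. The deposited values are log2 RMA signals, per the submitters' processing notes. The version of RMA and any further step of the authors are not given in the sources used here. The arrays came as 2 tables, normalized separately. An exon-level table held replicates 1 to 3 of each genotype, with 241576 probe sets. Its columns lay on separate scales, described below, and whether all of them were normalized together is not known here. A gene-level table held replicates 4 and 5, with 35556 probe sets. No column was left without a sample.

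Probe sets were named from the platform tables, with older symbols updated through the RefSeq gene table of the GRCm38.p6 assembly (2742 symbols in the exon-level table and 19 in the gene-level table). Of the exon-level probe sets 212097 had 1 gene, 4475 had several and 25004 had none. Of the gene-level probe sets these numbers were 21789, 1621 and 12146. Probe sets with several genes or none were left out of the gene values. A gene's exon-level value was the mean log2 over its probe sets (median 8 per gene), and its gene-level value was that of its brightest probe set. Of 19048 genes in both tables, the 12485 at or above the 30th percentile of mean log2 in each table were tested.

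Fits were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05). The main comparison was knockout minus wild type with the table as a fixed block. Each table was also fitted alone, the interaction of genotype and table was tested, and the probe sets of the exon-level table were tested at or above the 30th percentile. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over 29 lists, and again with an estimated correlation and with fry. These fits, lists, alternatives and the rule for named genes were fixed before the data were examined.

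The rule named Klf13 and its probe sets, up to 12 genes per direction with the largest change among those past the threshold with the same sign in each table (filled up to 5 by smallest p), up to 4 passing members of each list or else its member of smallest p, and Ccl5, Il4, Maf, Bcl2l1, Ifng, Il2, Cd4 and Cd8a. Predicted genes without a standard symbol were not named. Genes named outside the rule are said to be so.

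The lists were KLF and SP factors, KLF13 partner proteins, reported KLF13 target genes, chromosomal neighbours of Klf13, Th2, Th1 and cytotoxic, Th17, regulatory T cell, naive and memory T cell, and T cell receptor (TCR) signalling and activation genes, inhibitory receptors, chemokines and their receptors, cell cycle, apoptosis, cholesterol synthesis and uptake, glycolysis, oxidative phosphorylation, interferon response, stress and unfolded protein response, cytosolic ribosomal protein and sex-linked genes, CD4 and CD8 lineage genes, and markers of B and plasma cells, myeloid and dendritic cells, NK cells, basophils and mast cells, erythroid cells, and stromal and endothelial cells.

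The column medians of the exon-level table fell into separate scales, so the arrays were also grouped into 3 scale sets: replicate 1 of each genotype, replicates 2 and 3, and the gene-level table. Arrays whose median lay more than 0.5 log2 under the highest formed a set of their own. Fits with the scale sets as block were chosen after the main count had been seen, as were fits that joined this block with the median of probe sets, quantile normalization or the omission of knockout array 3. The rule for named genes was applied to the fit with scale sets as well.

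Other settings tried, also fixed beforehand, were quantile normalization within each table, subtraction of each array's median, the median or median polish of exon-level probe sets, the mean of gene-level probe sets, no filter or a 50th percentile filter on dim genes, eBayes with trend and robust, array weights, the replicate number as block, and leaving out each array. The fits were tested on simulated data with 50 changed genes per size. The simulated noise was independent, with means and spreads taken from the fit with scale sets as block and without array-wide distortions. The shares below are therefore best-case values and favour that fit. At a change of 2 log2 units 96% were recovered in the main comparison, 98% with scale sets as block, 46% in the exon-level table and 96% in the gene-level table; at 1 log2 unit these shares were 2%, 96%, 0% and 26%. The interaction with the table as block and the probe set tests recovered 0% even at 3 log2 units, and the interaction with scale sets as block 20% at 1 and 94% at 2. Among unchanged simulated genes the fit with scale sets as block made 10 false calls, against 0 in the main comparison, 0 in the exon-level table and 1 in the gene-level table. The number of arrays limits the precision of every value.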

Results

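Transcript levels were measured on Affymetrix arrays in CD3+ T cells from the spleens of male Balb/c mice aged 12 weeks. The cells had been activated for 4 days on plate-bound antibody to CD3 with soluble antibody to CD28. Wild-type mice (WT1 to WT5) were compared with mice lacking KLF13 (KO1 to KO5), a zinc-finger transcription factor known for its part in the late expression of the chemokine gene Ccl5 in T cells. An exon-level table held 3 arrays per genotype and a gene-level table held 2 per genotype. Exon-level column medians were 5.21 in WT1 and 5.23 in KO1, against 6.43, 6.42, 6.40 and 6.25 in WT2, WT3, KO2 and KO3, and those of the gene-level table lay between 4.18 and 4.30. Differences are therefore also given within these 3 scale sets. KO3 had an interquartile range of 3.10, against 3.43 to 3.56 in the other exon-level arrays. The 99th percentile was 12.2 and 12.3 in WT2 and WT3, and 11.4 and 11.6 in KO2 and KO3.

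The transcript of the targeted gene was compared first, as a check of the labels. Klf13 was at 0.549 of its wild-type level over both tables (log2 difference -0.86 ± 0.35, SE, 5 arrays against 5) and lower in 5 of 5 knockout arrays than in the wild-type arrays of their scale set. That difference did not pass (limma, adjusted p = 0.9998). In this fit limma gave each named gene that was tested the same standard error of 0.35. It is a value pooled over genes and not the spread of Klf13 itself. In the gene-level table alone Klf13 fell by 1.05 ± 0.15 (SE, 2 arrays against 2, adjusted p = 0.0129). The differences within the scale sets were -0.62 for replicate 1, -0.81 for replicates 2 and 3, and -1.05 in the gene-level table. With scale sets as block the standard error was 0.12 and the adjusted p was 0.0127, which became 0.0689 without WT2, 0.0507 without WT3, 0.0558 without WT4, 0.0641 without KO4 and 0.0539 without KO5. Of the exon-level probe sets of Klf13, 10564291 differed by -0.57 ± 0.63, 10564292 by -0.95 ± 0.72 and 10564293 by -0.71 ± 0.71 (SE, 3 arrays against 3), none past the threshold. Probe set 10564293 read 7.26 in KO3, beside 7.23 in WT2 and 7.17 in WT3. The place of the deletion relative to these probe sets is not given in the sources used here.

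The main comparison asked which transcripts differ in activated T cells that lack KLF13. Its pooled standard error of 0.35 was the same for each named gene, so its calls follow the size of the change and not each gene's own spread. Nkg7, a granule membrane protein of cytotoxic T cells and NK cells, fell to 0.218 of the wild-type level (log2 difference -2.20 ± 0.35, SE, 5 against 5, adjusted p = 2.47e-06). Il24, a cytokine made by Th2 cells, fell to 0.222 of that level (-2.17 ± 0.35, adjusted p = 2.47e-06). Il21, a cytokine of follicular helper and Th17 cells, fell to 0.283 (-1.82 ± 0.35, adjusted p = 0.000623), and Casp6, an executioner caspase, fell to 0.287 (-1.80 ± 0.35, adjusted p = 0.000662). Each was lower in 5 of 5 knockout arrays than in the wild-type arrays of the same scale set. Within the scale sets, in the order replicate 1, replicates 2 and 3, and gene-level table, the differences were -2.20, -1.88 and -2.51 for Nkg7, -0.96, -1.87 and -3.07 for Il24, -0.58, -3.02 and -1.25 for Il21, and -1.01, -2.25 and -1.74 for Casp6. These 4 were the genes called among 12485 tested, with 0 higher and 4 lower in the knockout arrays and 182 at an unadjusted p under 0.05. The count was 21 without WT1 and 21 without KO1, and without KO3 the adjusted p of Il21 was 0.218. Quantile normalization within each table ended the calls of Il24 (adjusted p = 0.755), Il21 (0.701) and Casp6 (0.0712), while Nkg7 passed under each alternative tried. Subtraction of array medians and the median of probe sets also ended the calls of Il24 (0.451 and 0.124) and Il21 (0.413 and 0.063), as did, for Il21, the replicate number as block (0.0896). Quantile normalization called 6 genes, 3 of them higher, and moved the median difference of all genes from -0.097 to 0.0047. In the gene order of GRCm38.p6, Nkg7 lies on the chromosome of Klf13 with fewer than 150 tested genes between them.

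**Figure D1:**
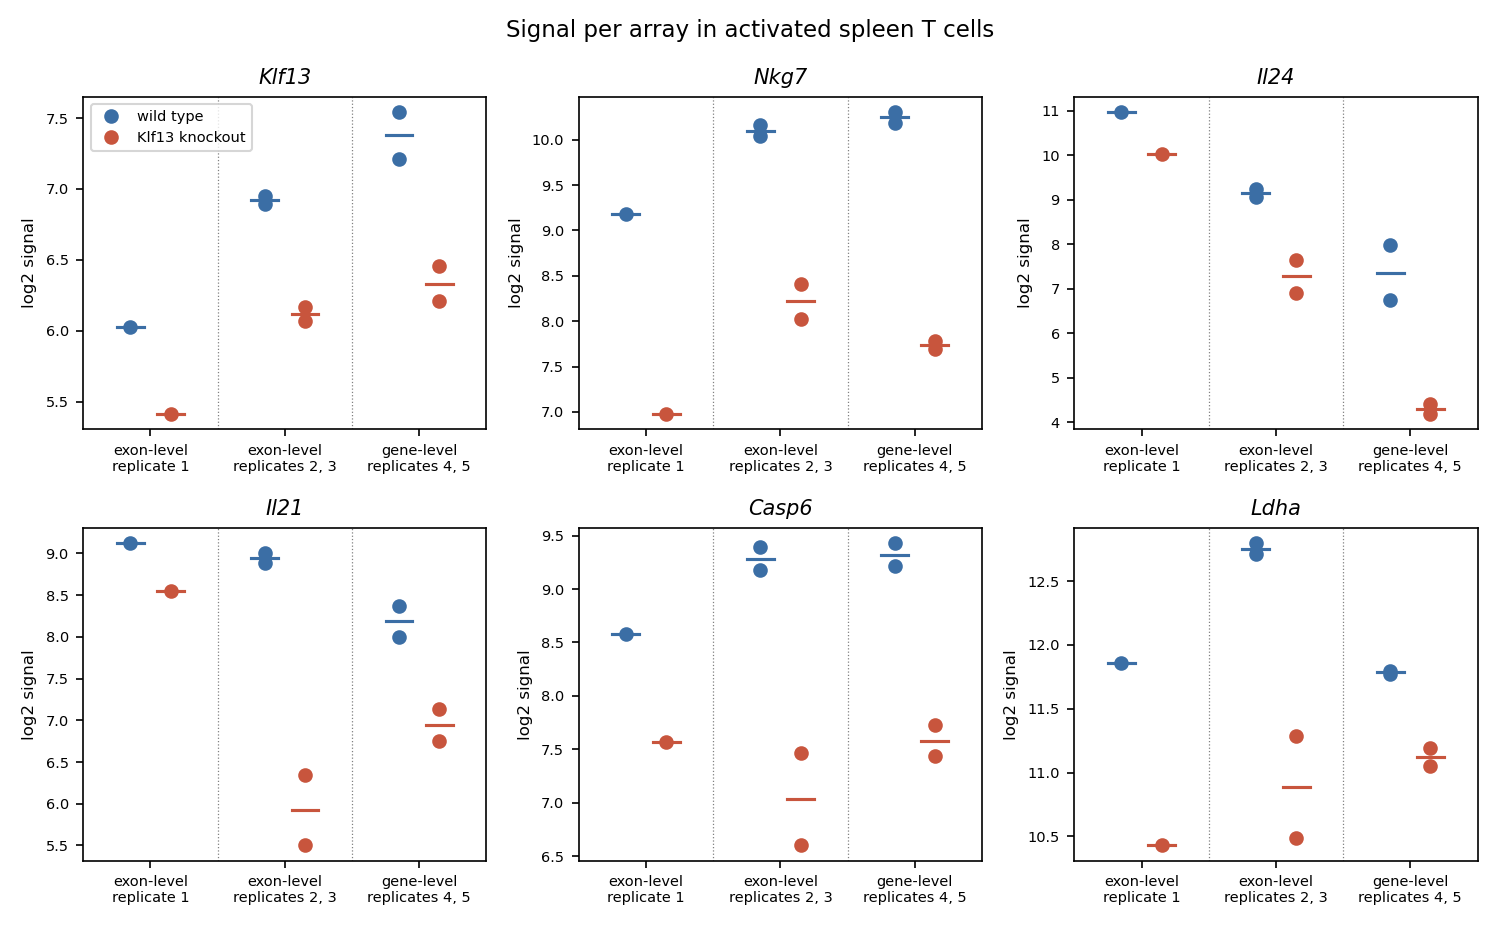
Log2 signal of Klf13, Nkg7, Il24, Il21, Casp6 and Ldha on each array, grouped by scale set and genotype; points are arrays and short bars are the mean of each genotype in each set. Nkg7 was lower in 5 of 5 knockout arrays than in the wild-type arrays of its set.

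Fewer than 5 genes passed in either direction, so the rule also named genes of smallest p, which did not pass over both tables. Slc17a6, a vesicular glutamate transporter, differed by -1.46 ± 0.35 (SE, 5 against 5, adjusted p = 0.0604). Among higher values were those of Cpt1c, the brain form of carnitine palmitoyltransferase (1.31, adjusted p = 0.162), Adh1, an alcohol dehydrogenase (2.29-fold, adjusted p = 0.407), and Nrn1, the neuritin gene (1.10, 0.632). B3gnt4, a glycosyltransferase (1.35, 0.133), and Gpr146, a G protein-coupled receptor (1.28, 0.212), were at 0.18 and 0.08 in the gene-level table, and B3gnt4 rests on 1 exon-level probe set. Of the genes always named, Il2, the T cell growth factor, was too dim to be tested, with differences of 0.43, -0.20 and 0.31 in the 3 scale sets.

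With the scale sets as block, a fit chosen after the count of 4 had been seen, more transcripts passed. Higher in the knockout arrays were Dapl1, expressed in naive and memory T cells (1.01 ± 0.13, SE, 5 against 5, adjusted p = 0.00792), Cpt1c (1.31 ± 0.19, 0.0127), Nrn1 (1.10 ± 0.17, 0.0196), Adh1 (2.29-fold, 0.0306) and Plxna3, a semaphorin receptor (0.84 ± 0.15, 0.0357). Lower, beside the 4 genes above, were Slc17a6 (-1.46 ± 0.11, adjusted p = 0.000258), Ctla2a, a cathepsin inhibitor (-1.45 ± 0.15, 0.00298), Sema4f, a semaphorin (-1.39 ± 0.19, 0.0122), Gpm6b, a membrane glycoprotein (-1.34 ± 0.18, 0.00827), Tnfrsf8, a receptor of activated lymphocytes (-1.25 ± 0.15, 0.00765), Ldha, lactate dehydrogenase A (-1.30 ± 0.22, 0.0306), and Cyp11a1, the enzyme that starts steroid synthesis (-1.21 ± 0.20, 0.0283). Snord33, a small nucleolar RNA with 1 exon-level probe set, was also lower (-1.34 ± 0.14, 0.00298). The remaining named risers were Qser1, Alpl, Slc6a16, Cpq, Hdgfl3 and the MHC class II chain H2-Aa, at 0.60 to 0.75. Il24 (adjusted p = 0.0173), Il21 (0.0444), Casp6 (0.00648) and Nkg7 (5.94e-05) passed here too. With median of probe sets and quantile normalization added, 27 of the 73 calls were kept, and those of Il24 (adjusted p = 0.170), Il21 (0.170), Cyp11a1 (0.0970), Qser1 (0.176), Cpq (0.198) and H2-Aa (0.130) were lost, while Slc6a16 was not tested there. The fit called 73 genes, 12 higher and 61 lower, with 1866 at an unadjusted p under 0.05, and 73 of 73 had the same sign in each scale set. This shared sign is largely built in, since the same arrays made the calls. The count was 12 without KO4, 13 without WT3, 14 without WT4, 15 without WT2, 18 without KO5, 25 without WT5, 28 without WT1 or KO1, 63 without KO2 and 362 without KO3. Nkg7, Slc17a6, Cpt1c, Snord33, Slc6a16, Ldha and Hdgfl3 lie within 150 tested genes of Klf13, where 9 of 300 genes were called (3.00%), against 2 of 725 (0.276%) on the rest of that chromosome.

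**Figure D2:**
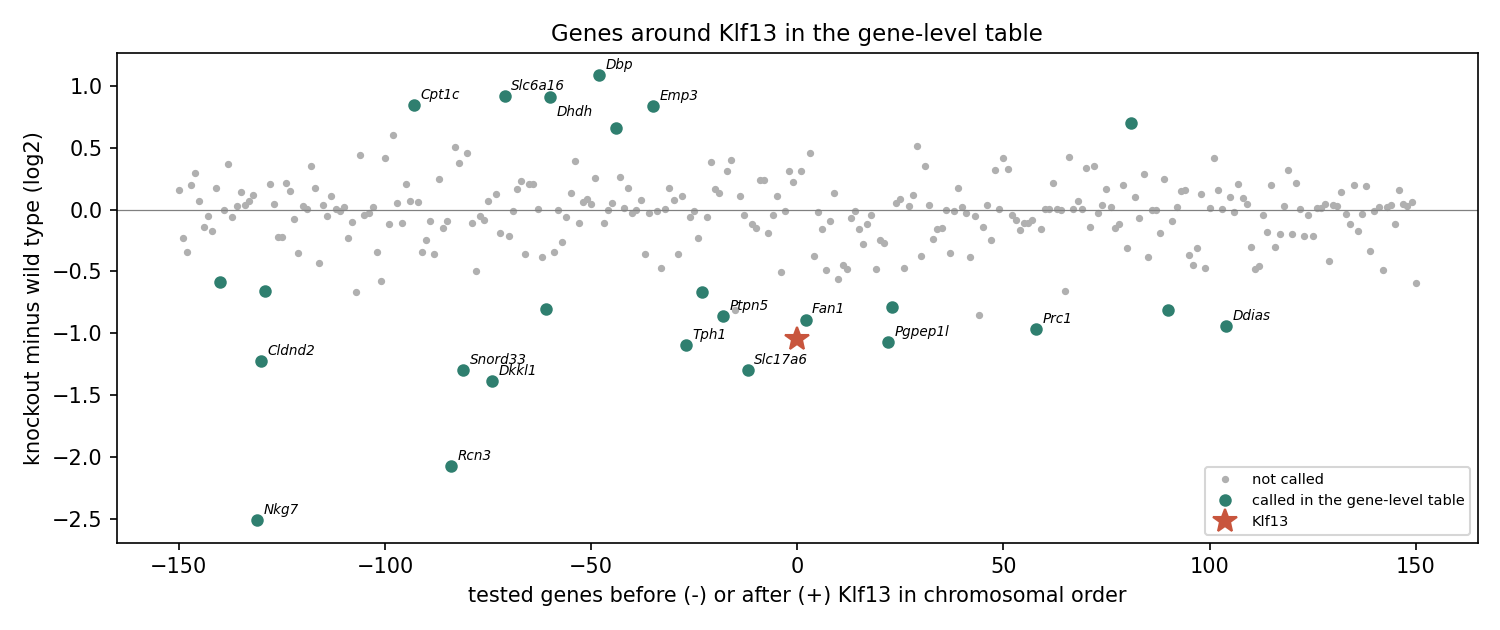
Log2 difference in the gene-level table (knockout minus wild type) of 150 tested genes on each side of Klf13, in the gene order of GRCm38.p6; each point is a gene and called genes are coloured. Of these genes 25 passed there.

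Each table was also tested alone. In the gene-level table Il24 fell by 3.07 ± 0.32 (SE, 2 arrays against 2, adjusted p = 0.00345), Nkg7 fell by 2.51 ± 0.13 (8.09e-05) and Casp6 fell by 1.74 ± 0.15 (0.00173). Dapl1 rose by 1.03 ± 0.17 (adjusted p = 0.0191), and Tox, a transcription factor of persistently stimulated T cells that was chosen after its value was seen, rose by 1.06 (0.00465). There 339 genes passed, 90 higher and 249 lower, with 529 genes passing without WT5 and 193 without KO4. After quantile normalization the split was 138 higher and 230 lower, and after subtraction of array medians 164 and 230. In the exon-level table limma called 0 genes, with 79 at an unadjusted p under 0.05, and it called 1 without WT1 and 8 without KO1. With scale sets as block it again called 0, with 1019 at an unadjusted p under 0.05. Of the 73 genes above, 63 also passed in the gene-level table, whose arrays were part of the fit that called the 73, so the overlap is partly built in.

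A test of whether the knockout difference itself differed between the tables called 0 genes (limma interaction, 15 at an unadjusted p under 0.05). With scale sets as block it called 0 (658 at an unadjusted p under 0.05), and without KO3 as well it called 121. With the table as block it called 1 without KO1. Among 169103 exon-level probe sets 0 passed in limma, with 2732 at an unadjusted p under 0.05, or 0 and 7898 with scale sets as block. Without single arrays 313 (WT2), 330 (WT3), 1162 (KO1), 380 (KO2) and 142 (KO3) probe sets passed. On simulated data the interaction with the table as block and the probe set tests recovered 0% of changed genes at each size, so their counts of 0 leave open whether differences exist. The interaction with scale sets as block recovered 20% at 1 log2 unit and 94% at 2.

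The Th2 list, cytokines and regulators of type 2 helper T cells, was lower in the knockout arrays as a group. Its 12 tested genes had a median difference of -0.89, with 11 of 12 lower, beside a median of -0.097 over all genes (camera, adjusted p = 4.20e-28). The list passed with an estimated correlation (adjusted p = 0.00192) and with fry (0.000338). Over all genes 1 member passed, Il24, and 10 fell when adjusted over the list alone. Medians within the scale sets were -0.79, -1.14 and -0.83. With scale sets as block 7 members passed, among them Il4, the cytokine that defines Th2 cells (-0.89 ± 0.17, SE, 5 against 5, adjusted p = 0.0471), which was at -0.41 in the gene-level table (adjusted p = 0.218). Other members that passed in that fit, chosen after their values were seen, were Gata3, the Th2 master regulator (-1.17, adjusted p = 0.00827), Il13 (-1.18, 0.00765), Batf (-1.17, 0.00827) and Irf4 (-0.88, 0.0173). With median of probe sets and quantile normalization added, Gata3 (0.0119) and Batf (0.0206) passed, but Il4 (-0.97, adjusted p = 0.130), Il13 (0.110) and Irf4 (0.504) did not. Ccr4, a chemokine receptor of Th2 cells, was at -0.95 (0.0540) and Maf, an activator of Il4, at -0.42 (0.159). The exception, the prostaglandin receptor Ptgdr2, also outside the rule, was at 0.11. Beside this list, markers of B cells had a median of 0.28 in the same arrays.

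Genes of glycolysis were also lower as a group. The median difference of the 16 tested genes was -0.63, with 16 of 16 lower (camera, adjusted p = 8.06e-15; estimated correlation, adjusted p = 0.0253; fry, 0.0067). Over all genes limma called 0 (6 at an unadjusted p under 0.05), and 1 fell when adjusted over the list alone. With scale sets as block Ldha (-1.30, adjusted p = 0.0306), the pyruvate kinase Pkm (-0.89, 0.0345) and the triosephosphate isomerase Tpi1 (-0.68, 0.0198) passed, of which Ldha was kept (0.0394) and Pkm (0.625) and Tpi1 (0.614) were lost with median of probe sets and quantile normalization added. Of the 16 genes 8 fell in the gene-level table, among them the hexokinase Hk2 (-1.05, adjusted p = 0.00489). Pkm, Tpi1 and Hk2 were chosen after their values were seen. Medians within the scale sets were -0.41, -0.73 and -0.60. Quantile normalization within each table moved the list's median from -0.63 to -0.34 and that of the Th2 list from -0.89 to -0.80, while both lists passed at the preset correlation but not with an estimated one (adjusted p = 0.340 and 0.317). With scale sets, median of probe sets and quantile normalization the estimated correlation gave an adjusted p of 0.0626 for glycolysis and 0.00469 for the Th2 list. Among random lists of equal brightness the glycolysis median lay at percentile 0.02 in replicate 1, 18.9 in replicates 2 and 3 and 0 in the gene-level table. In the exon-level table the brightest 5% of genes had a median difference of -0.58, against -0.07 in the gene-level table.

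Cell cycle genes, regulators and enzymes of DNA replication and mitosis, were lower as a group. All 31 tested genes had values below 0 over both tables, with a median of -0.46 (camera, adjusted p = 3.95e-11, but adjusted p = 0.570 with an estimated correlation). Over all genes 0 passed in limma (2 at an unadjusted p under 0.05), and 0 when adjusted over the list alone. In the gene-level table the median was -0.79 and 17 fell, or 27 adjusted over the list alone, among them the kinases Aurka (-1.11, adjusted p = 0.00698) and Plk1 (-1.03, 0.0165), chosen after their values were seen. Medians were -0.28 for replicate 1 and -0.10 for replicates 2 and 3, and among random lists of equal brightness the list lay at percentile 0 in replicate 1 and in the gene-level table but at 100 in replicates 2 and 3, where such lists had a median of -0.46. The member of smallest p over both tables was the cyclin Ccnd2 (-0.86 ± 0.35, SE, 5 against 5). Between the tables the list's medians of -0.79 (gene-level) and -0.14 (exon-level) differed at the preset correlation (camera, adjusted p = 2.68e-12, but 0.487 with an estimated correlation), one of 7 lists that did so, against 0 with an estimated correlation. Naive and memory T cell genes had a median of 0.09 over both tables (camera, adjusted p = 0.121) and of 0.45 in the gene-level table (adjusted p = 8.25e-07 with the preset correlation, but 0.469 with an estimated correlation), where Dapl1 and S1pr1, a receptor for lymphocyte exit from tissue, rose and 9 of 13 rose when adjusted over the list alone. S1pr1 was named as an exception to the rule, after its value was seen. After quantile normalization within each table the naive and memory list had a median of 0.17 over both tables. It then passed with the preset correlation (camera, adjusted p = 0.0017) but not with an estimated one (0.317). With the preset correlation 12 lists passed in the gene-level table, and 0 with an estimated correlation.

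**Figure D3:**
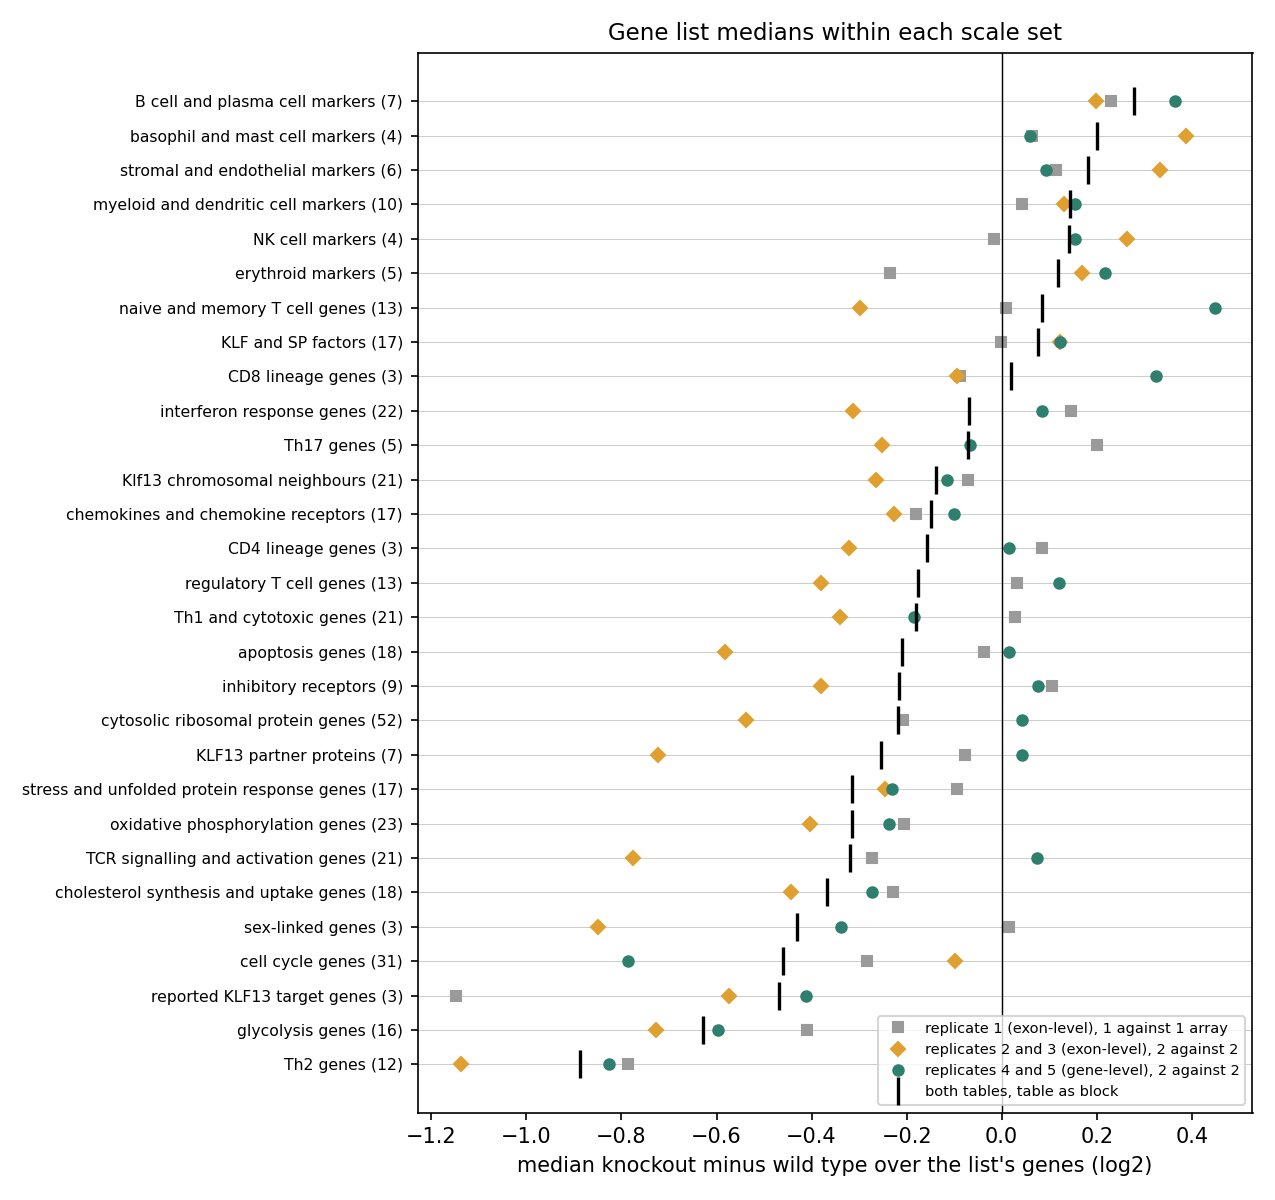
Median log2 difference (knockout minus wild type) of each of 29 gene lists; markers are the medians within each scale set, the vertical bar is the median over both tables, and the number of tested genes is in brackets. The Th2 list lies at -0.79, -1.14 and -0.83 in the 3 sets.

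Among other T cell lists, Th1 and cytotoxic genes fell with the preset correlation (21 genes, median -0.18, camera adjusted p = 0.0373, but adjusted p = 0.641 with an estimated correlation), with a median of 0.03 after quantile normalization. Of that list 1 gene passed, Nkg7, as when adjusted over the list alone. Granzyme B (Gzmb), chosen after its value was seen, was at -0.71 (adjusted p = 0.0471 with scale sets as block, but at 0.17, adjusted p = 0.824, with median of probe sets and quantile normalization added), and Ifng, the Th1 cytokine, at -0.30 (0.368), with 0.32, -0.40 and -0.50 in the scale sets. Of the 21 genes 8 were higher, among them the killer cell lectin-like receptors Klrd1 (0.81, adjusted p = 0.101 with scale sets as block), Klrk1 (0.74, 0.0897) and Klrc1 (0.63, 0.270), also chosen after their values were seen. Adjusted over the list alone, 3 were higher and 8 lower with scale sets as block, and 4 and 7 in the gene-level table. TCR signalling and activation genes had a median of -0.32 over both tables (21 genes, camera adjusted p = 0.000929, but adjusted p = 0.641 with an estimated correlation), of 0.07 in the gene-level table and of 0.03 after quantile normalization. In that list Il2ra, the high-affinity chain of the Il2 receptor, was at -1.10 over both tables and fell with scale sets as block (adjusted p = 0.0275) and in the gene-level table (-0.73, 0.0461), but not with median of probe sets and quantile normalization added to that block (-0.57, 0.211). Chemokine and receptor genes had a median of -0.15 (17 genes, adjusted p = 0.0339, but adjusted p = 0.641 with an estimated correlation) and of 0.03 after quantile normalization. Th17 genes (5 tested, median -0.07, mean -0.33, adjusted p = 0.0545), regulatory T cell genes (13 tested, -0.18, 0.226) and inhibitory receptors (9 tested, -0.22, 0.622) did not pass. Il21 was the Th17 member that passed, and Havcr2, an inhibitory receptor, was at -0.83 ± 0.35. The median of the Th17 list changed sign under quantile normalization and subtraction of array medians, and those of the regulatory and inhibitory lists under quantile normalization. Adjusted over the list alone, 1 gene fell in each of the Th17, regulatory and TCR lists, 1 rose and 1 fell among naive and memory genes, and 0 passed among chemokines (5 at an unadjusted p under 0.05) and inhibitory receptors (1). Over all genes limma called 0 members of these lists other than Nkg7 and Il21.

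Lists tied to KLF13 itself were compared next. The tested genes reported as KLF13 targets, Ccl5, Il4 and the survival gene Bcl2l1, had a median of -0.47 (3 genes, camera adjusted p = 0.0104, but adjusted p = 0.570 with an estimated correlation), with 0 called by limma over all genes, 1 at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone. Bcl2l1 was at -0.47 ± 0.35 (SE, 5 against 5) and lower in 5 of 5 knockout arrays. Ccl5, the chemokine also called RANTES, was at -0.18 ± 0.35, with -1.15, -0.38 and 0.50 in the scale sets, and at 0.03 after quantile normalization. Other KLF and SP factors rose as a group by a median of 0.08 (17 genes, adjusted p = 0.0167, but adjusted p = 0.641 with an estimated correlation), with Klf14 at 0.36. Their median was 0.12 in the gene-level table but -0.04 in the exon-level table, and 6 of 17 were lower over both. Proteins known to bind KLF13 had a median of -0.25 (7 genes, adjusted p = 0.0625), with the acetyltransferase Kat2b at -0.44 over both tables and 0.21 in the gene-level table. Chromosomal neighbours of Klf13 had a median of -0.14 (21 genes, adjusted p = 0.401). Among them the DNA repair nuclease Fan1 was at -0.70 over both tables and fell in the gene-level table (-0.89 ± 0.16, SE, 2 against 2, adjusted p = 0.0242). In each of these last 3 lists limma called 0 genes, as when adjusted over the list alone, with 2 neighbours and 0 of the others at an unadjusted p under 0.05.

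Lists of metabolism and stress had lower medians. Cholesterol genes were lower in 18 of 18 (median -0.37, camera adjusted p = 0.00316, but adjusted p = 0.641 with an estimated correlation), with the sterol sensor Insig1 at -0.51. After quantile normalization the median was -0.20. Oxidative phosphorylation genes had a median of -0.32 (23 genes, adjusted p = 0.000254, but adjusted p = 0.641 with an estimated correlation), with the ATP synthase subunit Atp5b at -0.79 over both tables and -0.25 in the gene-level table. Their median was -0.07 after quantile normalization. Stress and unfolded protein genes had a median of -0.31 (17 genes, adjusted p = 0.0150, but adjusted p = 0.641 with an estimated correlation), with the chaperone Hspa5 at -0.80, and the list was at 0.02 after quantile normalization. Ribosomal protein genes had a median of -0.22 (52 genes, adjusted p = 0.00408, but adjusted p = 0.697 with an estimated correlation), of 0.04 in the gene-level table and of 0.08 after quantile normalization. Their member of smallest p, Rps4x, was at -1.05 and rests on 1 exon-level probe set. Apoptosis genes (18 genes, median -0.21, adjusted p = 0.0960, Apaf1 at -0.51) and interferon response genes (22 genes, median -0.07 with a camera direction upward, adjusted p = 0.509, Usp18 at -0.65) did not pass. The median of the interferon list was at 0.03 after quantile normalization. In these 6 lists limma called 0 genes, and 0 when adjusted over the list alone, with 5 ribosomal, 2 oxidative phosphorylation and 1 stress gene at an unadjusted p under 0.05. In the gene-level table, where the brightest genes were at -0.07, the medians were -0.27 for cholesterol (camera, adjusted p = 0.000762, but 0.469 with an estimated correlation), -0.24 for oxidative phosphorylation (2.8e-05, but 0.469) and -0.23 for stress genes (0.00241, but 0.473). In replicates 2 and 3 the oxidative phosphorylation, stress and ribosomal lists lay at percentiles 98.2, 99.75 and 99.4 among random lists of equal brightness, so above most such lists. In the same order the percentiles were 0.59, 27.3 and 1.13 in replicate 1, and 0.07, 0.27 and 99.97 in the gene-level table.

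**Figure D4:**
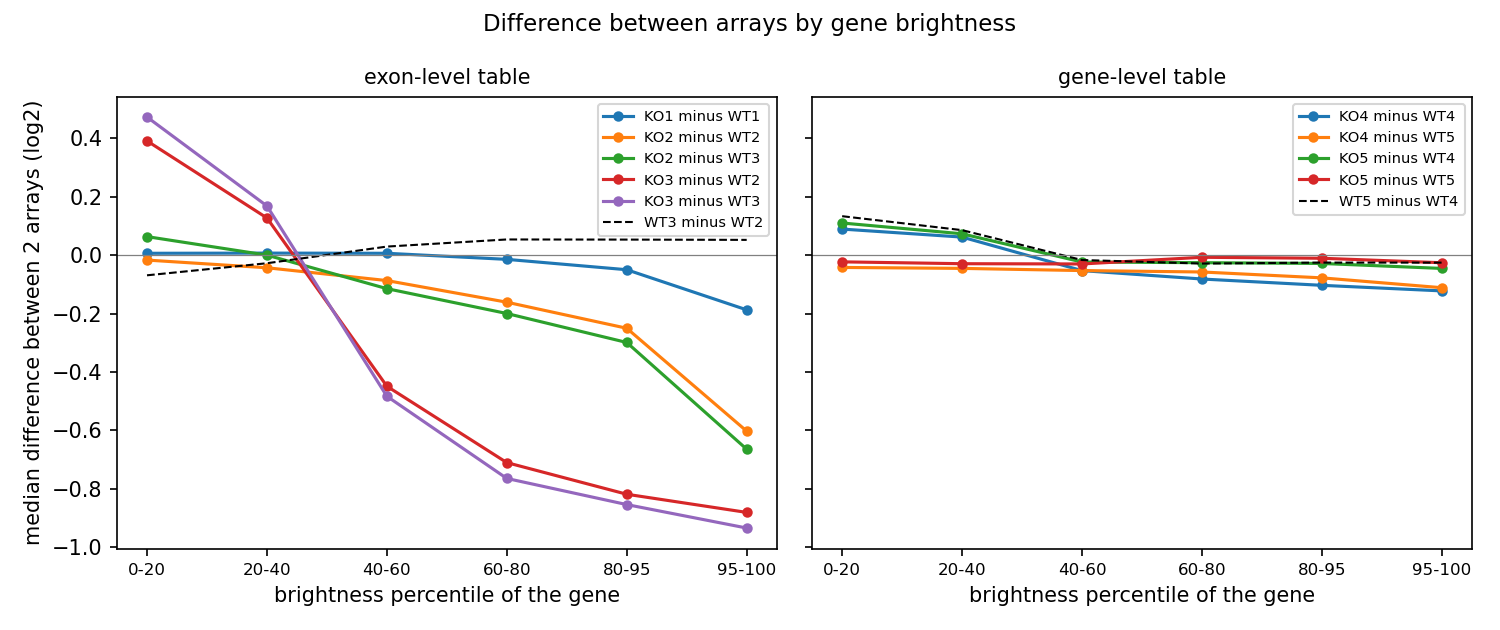
Median log2 difference between pairs of arrays in bins of brightness (percentile of mean signal), for the exon-level and the gene-level table; solid lines are knockout against wild-type pairs and dashed lines are wild-type pairs. The brightest 5% of genes lie at -0.58 in the exon-level and at -0.07 in the gene-level table.

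Markers of other spleen cells were compared as a measure of the make-up of the cultures. B cell markers rose as a group (7 genes, median 0.28, camera adjusted p = 0.000169, but adjusted p = 0.570 with an estimated correlation), and H2-Aa, also made by other antigen-presenting cells, was at 0.75 (adjusted p = 0.0471 with scale sets as block). Myeloid and dendritic (10 genes, 0.14, adjusted p = 0.0150), erythroid (5 genes, 0.12, 0.0339) and stromal markers (6 genes, 0.18, 0.0146) also rose with the preset correlation, but each had an adjusted p of 0.641 with an estimated correlation. Basophil and mast cell markers were at 0.20 (4 genes, adjusted p = 0.0320, but adjusted p = 0.570 with an estimated correlation). NK cell markers did not pass (4 genes, 0.14, 0.0845). Their members of smallest p were C1qa (0.30), Car2 (0.43), Sparc (0.42), Kit (0.34) and Klra3 (0.15). After quantile normalization the B cell (camera, adjusted p = 0.000264) and stromal (0.0184) lists passed. The myeloid (0.0597), erythroid (0.222) and basophil (0.125) lists did not. Among random lists of equal brightness the myeloid and erythroid lists lay at percentiles 40.5 and 41.0 in replicates 2 and 3. In the gene-level table both lay at 98.6. In replicate 1 the erythroid median was -0.23. The CD4 and CD8 lineage lists did not pass over both tables (3 genes each, medians -0.16 and 0.02, camera adjusted p = 0.657 and 0.345). With the preset correlation the CD8 list rose in the gene-level table (0.33, adjusted p = 0.00747, but 0.469 with an estimated correlation). It also rose after quantile normalization (0.28, 0.0184, but 0.317) and with scale sets, median of probe sets and quantile normalization (0.41, 0.00457, but 0.149). Cd4 was at -0.27 over both tables, 0.01 in the gene-level table and 0.09 after quantile normalization, and Cd8a was at -0.19, 0.33 and 0.20, while Crtam, a surface protein of activated CD8 cells, was at 0.32 and rose in the gene-level table (0.71, adjusted p = 0.0291). Sex-linked genes had a median of -0.43 (3 genes, adjusted p = 0.0339, but adjusted p = 0.641 with an estimated correlation), with Uty at -0.49. The CD4 list was at 0.02 after quantile normalization. In each of these lists limma called 0 genes over both tables, and 0 when adjusted over the list alone, with H2-Aa at an unadjusted p under 0.05. Of the 29 lists 18 passed with the preset correlation, 6 higher and 12 lower. With an estimated correlation 2 passed, the Th2 and glycolysis lists, as with fry.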

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

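The tests of array brightness, of gene order and of the Th2 and glycolysis lists were chosen only after the result was seen, as was the fit with scale sets as block; the regroupings of arrays and the test of oxygen-regulated genes were set before theirs.

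The arrays were regrouped within each table in every other way. For the main comparison 23 of 60 splits gave as many genes as the real 4, so chance is not excluded by this share. Each other split among these put WT1 and KO1 in the same arm and so mixes the scale sets into the comparison. Among splits that part WT1 from KO1, a restriction chosen after the counts were seen, the highest other gave 2. Over all 60 splits the highest other gave 2004, and it parts WT2, WT3 and KO2 from WT1, KO1 and KO3, which points to a structure of the exon-level arrays. The count with scale sets as block is 73. With that block 1 of 36 splits, the real split, gave as many (73, highest other 0). This argues against chance, but 1 of 36 is the smallest share these splits can give and the fit was itself chosen late. For the lists 1 of 60 splits gave as many as the real 18 (highest other 16), the smallest share these splits can give. The split with 16 still parts the exon-level arrays by genotype. The split of WT2, WT3, KO1, WT4 and WT5 from the rest gave 15, but it exchanges only WT1 and KO1. Such splits keep much of the genotype grouping and are a poor measure of chance. Among splits that part neither table by genotype the highest gave 11 (WT1, WT2, KO1, WT4 and KO4 from the rest). Most of the count is thus reached by other groupings, and with an estimated correlation 2 lists passed, so chance is not excluded for the lists one by one. Where the real count is 0 every split gives at least as many, so the share says nothing about chance: this holds for the interaction (60 of 60 splits, highest other 4226, a count that points to a structure of the arrays), the exon-level genes (10 of 10, highest other 5779) and the probe sets (10 of 10, highest other 37720). The highest of the last 2 was the split of WT1, KO1 and KO3 from the rest, and 10 splits would also be too few for a share under 0.05.

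Bright genes were lower in the knockout arrays of the exon-level table. In the gene-level table the brightest 5% of genes had a median of -0.074, against -0.58 in the exon-level table. A lower level of abundant transcripts in the knockout cells stays open all the same. The gene-level arrays were normalized by RMA and had 99th percentiles of 11.28 to 11.37, and such scaling could have removed a general fall. KO3 alone does not carry it, since these genes were at -0.60 in KO2 minus WT2. Of the probe sets above 13 in KO2, 91.5% lay under 10 in WT2 and WT3 (96.0% for KO1 against WT1, 0.0659% for WT2 against WT3), so bright outlier probe sets may have compressed the upper end of KO1 and KO2. The fall did not follow that share across the arrays. The brightest 5% of genes were at -0.19 in KO1 minus WT1, where the share was highest. In KO3 the share was 6.83%, yet these genes were at -0.88 and -0.93 against WT2 and WT3. What lowers the bright genes of KO3 stays open.

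Genes called with scale sets as block gathered around Klf13 on its chromosome. Chance position is argued against by a permutation p of 4e-05 for 9 called genes among the 300 nearest. Of the 25 genes there that the gene-level table called, 24 had at least 3 exon-level probe sets. By the median 85.7% of these probe sets moved the same way (100% for the 7 higher and 80% for the 17 lower genes, 60% for genes not called, 75% for genes called elsewhere), on arrays that had no part in the call. This argues against probe sets hit singly by sequence differences for the 24 genes as a group, though not for each of them. Cldnd2 (60%), Ptpn5 (61.1%), Prc1 (64.7%), Fan1 and Ddias (66.7% each) lay near the genes not called. For the lower genes the share is also favoured by exon-level differences that had a median of -0.145 over all genes. DNA of another strain carried along with the knockout allele may account for part of the called genes there, Nkg7, Ldha and Slc17a6 among them: their share was higher than on the rest of the chromosome (Fisher's exact test, 2-sided, p = 0.000439). The window was chosen after the positions had been seen, the labels name only Balb/c, no sequence was analysed here, and an effect of KLF13 on these genes stays open as well.

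The Th2 and glycolysis lists were lower in the knockout arrays, and compression of bright genes is argued against in the gene-level table, where both lay at percentile 0 of random lists of equal brightness, and in replicates 2 and 3 for the Th2 list (percentile 0). For the glycolysis list in replicates 2 and 3 compression stays open, at percentile 18.9 (median -0.73 against -0.65 of such lists). A lower share of T cells is argued against for the Th2 list in the gene-level table, where the TCR median was 0.07. There the Th2 median lay -0.90 from it (permutation p = 1e-05, the smallest the draws can give), genes not being independent replicates. In replicate 1 this difference was -0.51, but the TCR median was -0.27 with 1 array against 1, and such a share stays open. It stays open in replicates 2 and 3 as well, where the difference was -0.36 (permutation p = 0.0457). There the TCR median was -0.78 and bright genes were also lower. A weaker response to low oxygen stays open: the oxygen-regulated list gave a camera p of 0.24 with an estimated correlation and scale sets as block, and 0.192 in the gene-level table. An effect of the genotype on both programmes is a hypothesis that these values leave open, as are a different share of Th2 cells and a slower culture, which were not tested.

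Of 40 groups of arrays looked at, 5 had a value far from the others, where chance gives about 5%; values are each array minus the other genotype's mean in its scale set. Adh1 in KO2 was at 2.03, against 0.89 to 1.12 in the other knockout arrays. Maf in WT1 was at 0.75 (others 0.28 to 0.41) and in KO1 at -0.75 (others -0.40 to -0.28), which is the same pair seen from each side. Ifng in WT1 was at -0.32 (others 0.39 to 0.52). Il2 in KO3 was at -0.565 (others 0.17 to 0.43).

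Among 54 named genes, the tables moved in opposite ways on each array for Ccl5 (gene-level minus exon-level 1.14), Cd8a (0.86) and Rps4x (1.84). For Rps4x the gap came almost wholly from the exon-level table, where it was at -1.79, against 0.05 in the gene-level table. The interaction gave an adjusted p of 1 for each, in a test that recovered 0% of simulated differences, and with scale sets as block an adjusted p of 0.872 for each.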

How the results depend on the processing

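Alternatives with the scale sets as block, those that leave out KO3 together with another change, quantile normalization with an estimated correlation or with the replicate block, and the lists in the gene-level table alone were chosen after seeing the data; the others were planned. The count of 4 genes over both tables was 11 after subtraction of array medians, 2 with the median of probe sets, 7 with median polish, 1028 with array weights (whose estimation did not fully converge), 23 with the replicate number as block, 73 with scale sets as block, 31 with the median of probe sets as well, 36 with quantile normalization added, 172 with KO3 also left out, 362 with scale sets as block and KO3 left out, and 23 with quantile normalization and KO3 left out. It stayed between 4 and 6 under the other settings, but after quantile normalization 1 of the 6 was among the 4. The exon-level count of 0 was 1 with no filter, 3586 with array weights and 48 with the replicate block. The gene-level count of 339 was 517 with trend and robust and 660 with the replicate block. The interaction called 1 gene with no filter and 121 with scale sets as block and KO3 left out. Probe sets called were 3 with no filter, 2 with the 50th percentile filter and 19 with trend and robust. Whether replicate numbers pair the samples was not settled. Correlations were 0.39, 0.32, -0.30, -0.24 and -0.24 for replicates 1 to 5, against 0.12, 0.13, 0.62, 0.24 and 0.24 for the best other partner. Replicate 1 also carries its own scale, and with 2 arrays per genotype the values of replicates 4 and 5 are tied to each other. Of 29 lists, 18 in the main test, 2 passed with an estimated correlation, 0 with that and quantile normalization, 2 with fry and 8 with scale sets, median of probe sets and quantile normalization. Klf13 passed with array weights (-1.02, adjusted p = 1.78e-08), the replicate block (-0.86, 0.0356), scale sets (-0.86, 0.0127), scale sets with median and quantile normalization (-0.86, 0.0357) and scale sets without KO3 (-0.86, 0.00145). Values that changed sign were those of Ccl5 (0.033 with quantile normalization, 0.26 with array weights, 0.058 with scale sets, median and quantile normalization), Cd8a (0.20, 0.090 and 0.24 in the same order), Cd4 (0.092 with quantile normalization), Atp5b (0.023) and Ifng (0.015), both with scale sets, median and quantile normalization. None of these 5 had passed. Leaving out each array in turn gave 4 to 21 genes over both tables, 0 to 8 in the exon-level table, 193 to 529 in the gene-level table, 0 to 1 for the interaction, 0 to 1162 probe sets, 14 to 18 lists, Klf13 at -1.04 to -0.75, the Th2 median at -1.01 to -0.80, the glycolysis median at -0.69 to -0.59, Ccl5 at -0.31 to 0.064 and Klra3 at -0.10 to 0.37. Of the other values of named genes, 526 kept their direction and their side of the threshold, 129 came to pass and 10 no longer passed; leaving out arrays, these numbers were 505, 22 and 1. The cause was not tested. Dim genes, under the 30th percentile, were left out because signal near background limits what can be seen; without that filter the count over both tables did not move beyond the range above.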

Other observations

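The genes in this part were chosen after their values were seen, and the list of oxygen-regulated genes was drawn up after Hk2 and other oxygen-regulated genes had been seen to fall. That list was fixed before its test, but Rora was already a tested member of the Th17 list.

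Some members of the T cell lists passed in the gene-level table (limma, 2 arrays against 2) without passing over both tables with the table as block; with scale sets as block Ccr8 and Gzmb passed (adjusted p = 0.0471 for each), though not with median of probe sets and quantile normalization added (0.265 and 0.824). Lower in the knockout arrays were Ccr8, a chemokine receptor of Th2 and regulatory T cells (-1.12, adjusted p = 0.00465), Gzmc, a granzyme (-0.99, 0.0353), Gzmb (-0.74, 0.0248) and Serpinb9, an inhibitor of granzyme B (-0.79, 0.0172). Higher were S1pr1 (0.82, 0.0129), Ikzf2, a transcription factor of regulatory T cells (0.72, 0.0279), Itgae, an integrin of tissue-resident T cells (0.66, 0.0287), and Btla, an inhibitory receptor (0.66, 0.0425). Over both tables these values were -0.81 for Ccr8, -0.76 for Gzmc, -0.71 for Gzmb, -0.48 for Serpinb9, 0.16 for S1pr1, 0.42 for Ikzf2, 0.18 for Itgae and 0.27 for Btla.

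Of 15 oxygen-regulated genes 13 were tested and 11 were lower in the knockout arrays, with a median of -0.13 with scale sets as block and of -0.26 in the gene-level table. Higd1a, a mitochondrial protein induced by low oxygen, fell in the gene-level table (-0.71, adjusted p = 0.0207), and it was the only member called there. Without Rora, which is also in the Th17 list, camera with an estimated correlation gave p = 0.188 with scale sets as block and 0.171 in the gene-level table (12 genes, medians -0.15 and -0.26).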
